A study of Caenorhabditis elegans with 8 samples.

How the data were processed

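Total RNA from whole Caenorhabditis elegans worms at the L4 larval stage was measured on 8 one-colour Agilent arrays, 4 of the wild-type strain N2 and 4 of cdk-8(tm1238) null mutants. Each array came from its own worm growth, per the labels' protocols. RNA was extracted with Trizol, amplified and labelled with Cy3, per the labels' protocols.

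The values compared were the log2 values of the deposited series table, which held 43603 probes for each of the 8 arrays. The submitters' processing notes name limma without a version and without saying which steps it ran. The scale of the table was therefore worked out from the values. Over the 4 mutant arrays, the Spearman correlation of the table with the scanner's median spot signal lay between 0.999986 and 0.999999, and the slope on the log2 scale lay between 0.984 and 1.03. All 8 columns shared 1 distribution, with a median of 9.28 to 9.29 and a 75th percentile of 12.09, as quantile normalization gives. No local background had been subtracted and genes had not been centred, so that the fold change of a dim gene is understated. The direction was set by the group labels, as mutant minus wild type.

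Scanner files were used for the 4 mutant arrays, and those of the wild-type arrays were not analysed here. They hold spot intensity values and flags written by Agilent Feature Extraction 9.5.1.1, per the file headers. Each array had 45220 spots, of which 1417 were controls and 153 of these negative controls. The share of probes well above background was 74.4%, 72.7%, 73.0% and 62.0% on mutant arrays 1 to 4. Between 1 and 2 probes were saturated on each. The column of mutant replicate 4 had 4214 empty cells, 9.66% of the probes, and each of these probes carried an outlier flag of the scanner software. The flagged probes of mutant arrays 1 to 3, which numbered 1308, 1377 and 1787, had kept their values. The lowest table value among probes well above background averaged 5.91 (log2) over the mutant arrays. The number of arrays limits the precision of every value.

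Probes were paired with genes through the accessions column of the scanner files and the RefSeq gene table of assembly WBcel235, which was used for names and for the order of neighbouring genes only. Exactly 1 gene was named by 35419 probes, of which 34114 matched the RefSeq table and 1305 kept an older sequence name. Another 1277 probes named several genes and 6907 named none, and both kinds were left out of the gene test. Where a gene had several probes (5610 of 20537 genes), the probe with the highest mean over all 8 arrays stood for it. Probe coordinates are those of build ce4 in the scanner files.

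Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values and the group as the only term. All tests were 2-sided. P-values were adjusted by the Benjamini-Hochberg method over all 20537 genes, and a gene was called changed at an adjusted p under 0.05. The words rose and fell are used of such genes only. No filter on dim genes was applied. In simulated data made from the spread of these arrays, with the same 20537 genes, the comparison of mutant with wild type recovered 55.2% of 67 genes changed 1.5-fold, 97.0% of 67 genes changed 2-fold and 97.0% of 66 genes changed 4-fold, with 10 false calls. A simulated shift of 0.5 (log2) in the proteasome list was called, and 0 other lists were. Genes were simulated independently of each other, while the correlation estimated for the proteasome list in the real arrays was 0.51. The simulation therefore cannot show how often lists of correlated genes are called falsely.

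Before the data were examined, 43 gene lists were fixed. They covered the Mediator kinase module and the other Mediator subunits; EGF, Notch and Wnt signalling and vulval genes; cuticle, moulting and hedgehog-related genes; germline, sperm, oocyte, yolk, embryo and male genes; the cell cycle and histones; lipid and detoxification enzymes; stress, insulin and immune genes; neuron, muscle, gut and epidermis markers; receptor and F-box families; and housekeeping complexes. Each list was tested against all other genes with camera, with a preset correlation of 0.01 between genes, over the members with a value on all 8 arrays. P-values were adjusted over the 43 lists. Camera with an estimated correlation and fry, which asks whether the members of a list move one way on balance without comparing them with other genes, were run as alternatives. The genes named in the text were also chosen by a rule fixed before the data were examined. It takes the 4 kinase module genes, the 10 largest rises and 10 largest falls among genes with a 3- or 4-letter name whose groups did not overlap, the 3 largest rises and 3 largest falls among the other genes, and up to 4 members per described list in order of p.

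The alternatives were other normalizations of the table (a shift to a common 75th percentile, quantile and cyclic loess normalization), leaving out the dimmest 25% of genes, the mean of all probes of a gene, every probe tested, an intensity trend with robust variance, array weights, the replicate number as a block, each array left out in turn, Welch's test and an adjusted p under 0.01. After the data were examined, normexp correction of the table with an offset of 16, genes detected on the arrays, genes with all 8 values and the removal of flagged spots on every mutant array were added. Figures were drawn with matplotlib 3.10.9.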

Results

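Expression was measured in synchronized L4 larvae of wild-type C. elegans and of cdk-8(tm1238) mutants, with 4 arrays per strain. CDK-8 is the kinase of the Mediator kinase module, a part of the Mediator complex that bridges transcription factors and RNA polymerase II. The comparison asked which transcripts differ between worms without a working cdk-8 gene and wild-type worms at a stage before embryos are present. Signals are given as log2 of the quantile-normalized spot signal, with the mean ± SD over 4 arrays, and changes as mutant minus wild type with the standard error from limma. Adjusted p-values are those of limma over all genes unless a list test is named.

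The targeted gene was examined first. The cdk-8 probe, on chromosome I at 8713539 to 8713598 in build ce4, gave 12.41, 12.45, 12.59 and 12.23 on wild-type replicates 1 to 4 and 13.11, 12.92, 12.89 and 13.11 on mutant replicates 1 to 4. The cdk-8 signal was thus 12.42 ± 0.15 in wild type and 13.01 ± 0.12 in the mutant, a rise of 0.59 ± 0.094 (adjusted p = 0.00106). Where the deletion lies relative to this probe was not given in the sources used here, so the signal checks nothing about the strain labels. The other genes of the kinase module did not pass the test. The change was 0.11 ± 0.069 for cic-1, which encodes cyclin C (adjusted p = 0.251), 0.25 ± 0.13 for let-19 (adjusted p = 0.170) and 0.13 ± 0.13 for dpy-22 (adjusted p = 0.475), the last 2 encoding the Med13 and Med12 subunits. The module as a list of 4 was not past the camera threshold (adjusted p = 0.387). Among 23 measured subunits of the Mediator head, middle and tail, 3 rose, 2 fell and 18 did not pass (camera adjusted p = 0.734), and 1 rose and 2 fell adjusted over the list alone. The rises included mdt-26 (0.36 ± 0.074, with its other 11 probes at 0.17 to 0.35) and mdt-15 (0.27 ± 0.081), and the falls were mdt-18 (-0.49 ± 0.076) and mdt-1.2 (-0.24 ± 0.062). The second mdt-15 probe gave -0.01, and the mdt-15 call was lost without wild-type replicate 1, 2 or 3 or mutant replicate 2 or 4 (adjusted p between 0.0561 and 0.0777) and with the mean of its 2 probes (0.124). That of mdt-1.2 was lost without wild-type replicate 1 or 2 (adjusted p = 0.0503 and 0.0501).

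**Figure D1:**
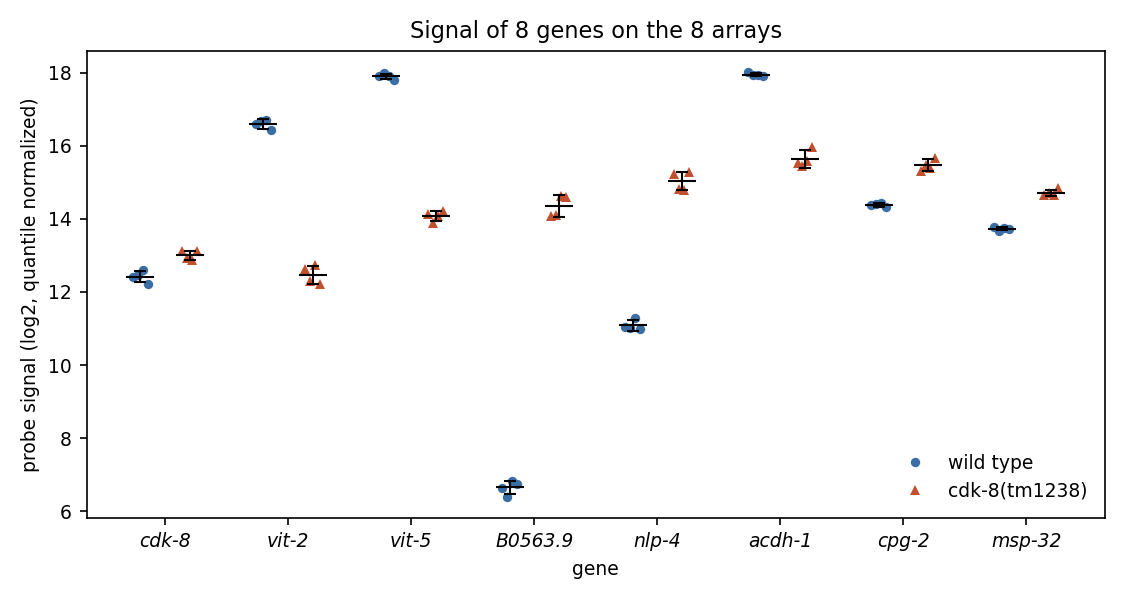
Probe signal (log2, quantile normalized) of 8 genes on the 8 arrays, with circles for wild type and triangles for cdk-8(tm1238), and bars for the mean ± SD over 4 arrays. The vit-2 signal averaged 16.60 in wild type and 12.46 in the mutant, while B0563.9 averaged 6.65 and 14.35.

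Expression differed in 7753 of 20537 genes (37.8%), of which 4170 were higher and 3583 lower in the mutant. At least a 2-fold difference was estimated for 1369 of them, 891 higher and 478 lower, so that 65.1% of these were higher. The small excess of rises among all changed genes turned when each probe was tested, with 6846 probes higher and 7031 lower, so no excess is claimed. The values of the 2 strains did not overlap in 8057 genes (39.2%), against 2.86% given by chance for 4 against 4. The 1983 genes with a value on 3 mutant arrays only were included, and for them chance gives a larger share. The median change over all genes was 0.01, and the median standard error was 0.096. Of the changed genes, 329 were not well above background on any mutant array, including 32 of the 478 that were 2-fold lower. Another probe was called the opposite way in 28 of the 1994 changed genes that had more than 1 probe.

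The largest rises among named genes were in nlp-4, a neuropeptide-like protein gene (3.95 ± 0.13, 15.5-fold, adjusted p = 2.46e-07), and acd-2 (3.86 ± 0.087, 14.5-fold, adjusted p = 3.78e-08), a degenerin-family ion channel gene. They were followed by pals-32 (3.70 ± 0.15), the saposin-like gene spp-12 (11.4-fold), delm-2 (11.2-fold), which is also of the degenerin family, the acyltransferase gene oac-11 (at least 9.97-fold) and the cytochrome P450 gene cyp-35B3 (at least 9.07-fold). The chemoreceptor gene srh-177 rose at least 7.62-fold, and lea-1, a gene of the late embryogenesis abundant proteins linked with desiccation tolerance, rose 7.30-fold. The fatty acid and retinol binding protein gene far-3 rose 7.24-fold on the probe used, while its other 3 probes gave changes between 0.08 and 0.16 (log2), so its rise is uncertain. Each of these 10 genes had an adjusted p of 2.34e-06 or less. Larger rises occurred among genes known by sequence name only. B0563.9, whose probe lies on chromosome X at 9168893 to 9168952 in build ce4, went from 6.65 ± 0.19 to 14.35 ± 0.30, a rise of at least 207-fold (adjusted p = 2.80e-08), and its other 4 probes gave changes of 7.86 to 8.04 (log2). C36C5.15 rose 66.8-fold and K03D3.2 rose 52.6-fold, each measured by 1 probe. The folds of srh-177, oac-11, cyp-35B3 and B0563.9 are lower limits, because wild-type detection was not checked, and few genes at their wild-type signals were well above background on 3 or more mutant arrays (0% for the first 3 and 12.9% for B0563.9).

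The deepest falls among named genes were in the vitellogenin genes vit-2, vit-3, vit-4 and vit-5, which encode yolk proteins made in the intestine of the hermaphrodite. The vit-2 signal went from 16.60 ± 0.13 to 12.46 ± 0.25, a 17.6-fold fall (adjusted p = 1.43e-07), on a probe on chromosome X at 5106044 to 5106103 in build ce4. The changes of vit-3, vit-4 and vit-5 were 15.7-fold, 14.8-fold and 14.1-fold downward. Because these copies are similar in sequence, their separate values are uncertain. Next came nspb-5 (12.9-fold lower), the aspartyl protease gene asp-17 (12.8-fold lower), irg-1, an infection response gene (7.61-fold lower, with its other 5 probes at -2.49 to -2.79), the lipase-related gene lips-6 (7.15-fold lower), and nspb-8 and nspb-6, both 7.02-fold lower. The 3 nspb genes belong to a nematode-specific peptide family of similar copies and are uncertain one by one. By sequence name, F33H12.7 fell 29.9-fold, with its other 2 probes at -4.61 and -4.73, and Y48E1B.8 fell 18.3-fold. F07C6.6 fell at least 9.29-fold, but was well above background on only 1 mutant array, and its second probe gave -1.82.

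**Figure D2:**
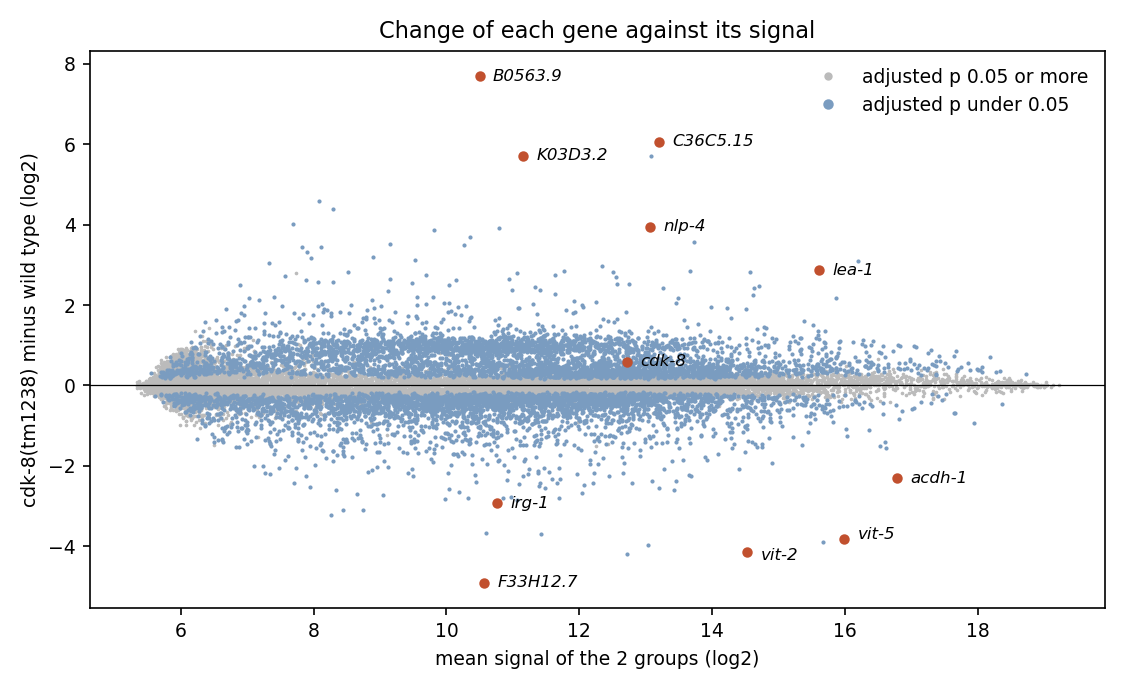
Change of each of the 20537 genes (mutant minus wild type, log2) against the mean signal of the 2 groups (log2), with genes past an adjusted p of 0.05 in blue, the rest in grey and 11 genes named in the text in red. B0563.9 has the highest change, at 7.69, and F33H12.7 the lowest, at -4.90.

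Of the 43 gene lists, 13 passed the camera threshold, 5 of them higher and 8 lower in the mutant, and 0 passed with an estimated correlation. By fry, which does not compare a list with other genes, 24 lists passed. Those past fry but not camera were, with the fry adjusted p, the cell cycle (0.00106), ABC transporters (0.0047), male genes (0.0101), the Mediator kinase module (0.0227), F-box genes (0.0235), epidermal antimicrobial peptides (0.0285), UDP-glucuronosyltransferases (0.0288), and EGF and insulin pathway genes, C-type lectins and chemoreceptors, which are given with their lists or among the alternatives. The adjusted p with an estimated correlation is therefore given with each list.

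Sperm genes rose almost without exception. All 20 measured major sperm protein genes, whose products build the cytoskeleton of the crawling sperm, rose (camera adjusted p = 3.21e-07; adjusted p = 0.478 with an estimated correlation). They included msp-32 (0.98 ± 0.065), msp-142 (0.94 ± 0.071), msp-64 (0.94 ± 0.082) and msp-152 (0.83 ± 0.071, 3 mutant arrays). These genes are near-identical, so single members are uncertain, and the second msp-32 probe gave -0.15. Of 42 other sperm genes, 38 rose and 0 fell (camera adjusted p = 3.82e-15; adjusted p = 0.194 with an estimated correlation), among them ssp-36 (1.06 ± 0.068), msd-4 (1.04 ± 0.078), ssp-31 (1.08 ± 0.081) and fer-1 (0.96 ± 0.073), which is needed for sperm membrane fusion. Adjusted over the list alone, 20 and 38 members rose.

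Germline genes outside spermatogenesis were higher too. In the list of oocyte and eggshell genes, 16 of 21 rose and 3 fell (camera adjusted p = 0.00108; adjusted p = 0.478 with an estimated correlation). The rises were led by cpg-2 (1.08 ± 0.085) and cpg-1 (0.83 ± 0.084), which encode chondroitin proteoglycans of the eggshell, with the chitin synthase gene chs-1 (0.61 ± 0.057) and egg-3 (0.53 ± 0.059). The 3 falls, chosen for naming after their values were seen, were in perm-2 (-0.53 ± 0.14) and perm-4 (-0.40 ± 0.075), which act in the eggshell permeability barrier, and lin-41 (-0.32 ± 0.067). Of 38 genes of germline mitosis and meiosis, 25 rose and 0 fell (camera adjusted p = 3.97e-07; adjusted p = 0.194 with an estimated correlation). Examples were zim-2 (0.76 ± 0.073) and zim-3 (0.49 ± 0.062), zinc finger genes of chromosome pairing, the RNA helicase gene glh-4 (0.57 ± 0.068) and the synaptonemal complex gene syp-3 (0.45 ± 0.057). Of 25 histone genes, 17 rose and 0 fell (camera adjusted p = 8.37e-05; adjusted p = 0.478 with an estimated correlation), with his-18 (1.94 ± 0.16), his-17 (1.63 ± 0.082, 3 mutant arrays), his-68 (1.35 ± 0.12) and his-3 (1.14 ± 0.094), all copies of repeated gene clusters and uncertain one by one. Adjusted over each list alone, 16 oocyte, 27 germline and 18 histone genes rose. The signal of sperm genes in mutant replicate 4 was above that of the other mutant arrays, by 0.39 for the major sperm proteins and 0.23 for the other sperm genes, but so was that of lists without a shift between strains, such as the respiratory chain (0.39) and the proteasome (0.31).

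All 6 vitellogenin genes fell (camera adjusted p = 3.97e-07; adjusted p = 0.194 with an estimated correlation), with a median change of -3.85, and all 6 did adjusted over the list alone. Of 49 glutathione S-transferase genes, which act in detoxification, 27 fell and 6 rose (camera adjusted p = 6.92e-06; adjusted p = 0.194 with an estimated correlation), and 28 fell adjusted over the list alone. Members with a fall were gst-14 (-2.19 ± 0.065), gst-12 (-1.71 ± 0.060), gst-38 (-2.38 ± 0.11) and gst-13 (-1.85 ± 0.11). Other detoxification families moved in both directions. Of 79 cytochrome P450 genes, 25 rose and 25 fell (camera adjusted p = 0.734), with cyp-35B3 and cyp-37B1 (2.07 ± 0.091) higher and cyp-13A6 (-2.23 ± 0.062) and cyp-35D1 (-1.47 ± 0.066) lower. Of 66 UDP-glucuronosyltransferase genes, 23 rose and 23 fell (camera adjusted p = 0.669), with ugt-53 (2.70 ± 0.093, 3 mutant arrays) and ugt-34 (2.19 ± 0.073, with its other 2 probes at 0.86 and 1.98) higher and ugt-63 (-2.47 ± 0.068) and ugt-1 (-1.56 ± 0.069) lower. Adjusted over the list alone, 25 cytochrome P450 genes rose and 28 fell, and 27 UDP-glucuronosyltransferase genes rose and 23 fell.

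Genes of fatty acid oxidation were lower on balance, with 15 of 47 falling and 5 rising (camera adjusted p = 0.0416; adjusted p = 0.910 with an estimated correlation), and 16 falling adjusted over the list alone. The falls were 5.36-fold for acox-1.2, a peroxisomal acyl-CoA oxidase gene, 4.97-fold for acdh-1, an acyl-CoA dehydrogenase gene of the propionate breakdown shunt, 4.79-fold for acs-2, an acyl-CoA synthetase gene, and 3.93-fold for acdh-2. The call of this list was lost without wild-type replicate 1 or 3 (adjusted p = 0.0513 and 0.0566), without mutant replicate 1 or 2 (0.151 and 0.0790), and in 3 other settings given with the alternatives. Among 27 genes of fatty acid synthesis and desaturation, 9 rose and 2 fell (camera adjusted p = 0.814). The desaturase genes fat-7 (1.31 ± 0.068, 3 mutant arrays) and fat-5 (0.39 ± 0.054) and the elongase gene elo-7 (0.77 ± 0.100) rose, and the acyltransferase gene dgat-2 (-0.95 ± 0.10) fell, and the counts were the same adjusted over the list alone.

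Part of the neuronal transcripts fell. Of 31 neuron markers, which include genes of single transmitter classes, 15 fell, 0 rose and 16 did not pass (camera adjusted p = 0.000514; adjusted p = 0.194 with an estimated correlation). The falls included tbh-1 (-1.12 ± 0.099), which encodes the octopamine-making enzyme, unc-25 (-0.79 ± 0.10), the glutamate decarboxylase gene of GABA neurons, bas-1 (-0.60 ± 0.074), an amine biosynthesis gene, and unc-119 (-0.51 ± 0.077, 3 mutant arrays). Of 31 genes for FMRFamide-like neuropeptides, 14 fell and 2 rose (camera adjusted p = 0.0161; adjusted p = 0.478 with an estimated correlation), led by flp-1 (-0.72 ± 0.090), flp-24 (-0.76 ± 0.086, 3 mutant arrays), flp-17 (-1.09 ± 0.14) and flp-33 (-0.94 ± 0.13). Adjusted over each list alone, 15 and 14 fell. The mean of the neuron markers was lower by 0.23 (-0.23 ± 0.073, SE over arrays), but the highest mutant array (11.49) reached the lowest wild-type array (11.47).

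**Figure D3:**
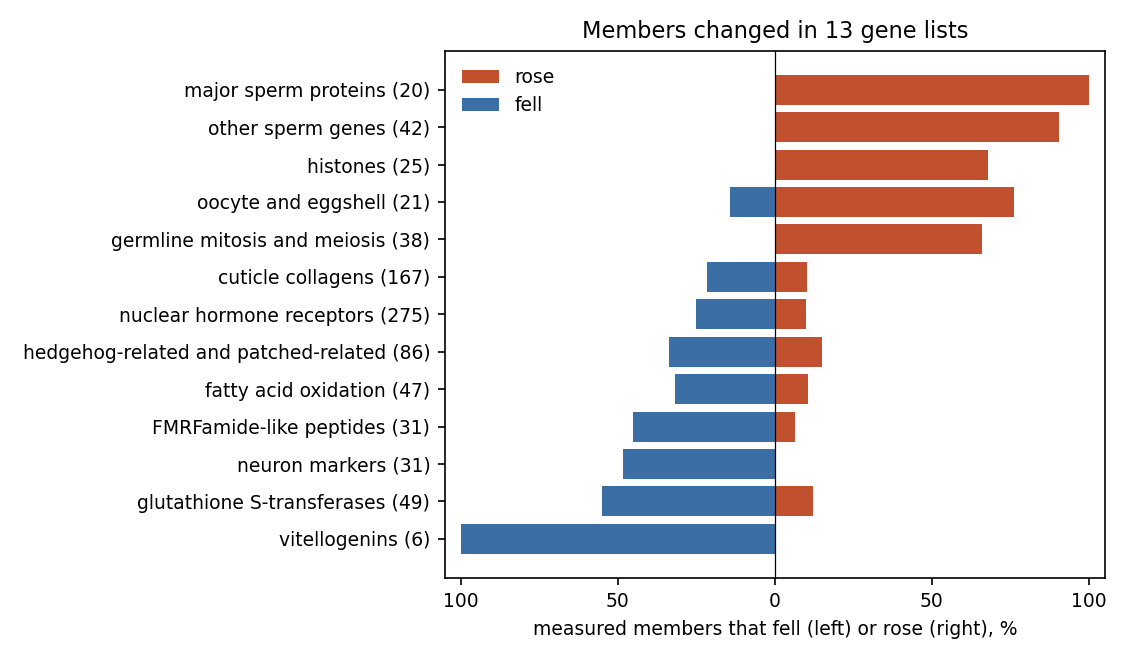
Percent of the measured members of each of the 13 gene lists past the camera threshold that fell (blue, to the left) or rose (red, to the right) in cdk-8(tm1238) mutants, with the number of measured members in brackets. The 20 major sperm protein genes all rose and the 6 vitellogenin genes all fell.

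Cuticle collagen, hedgehog-related and nuclear receptor families held falls and rises together. Of 167 cuticle collagen genes, 36 fell and 17 rose (camera adjusted p = 0.0247; adjusted p = 0.910 with an estimated correlation), with col-143 (-2.33 ± 0.19), col-61 (-1.38 ± 0.065), dpy-17 (-1.16 ± 0.090) and col-139 (-1.16 ± 0.092) lower. That call was lost without mutant replicate 1 (adjusted p = 0.123). Of 86 hedgehog-related and patched-related genes, 29 fell and 13 rose (camera adjusted p = 0.0247; adjusted p = 0.672 with an estimated correlation). Among these, grl-27 (-2.66 ± 0.13) and grl-6 (-1.43 ± 0.079) fell and ptr-22 (1.72 ± 0.10) rose, and grl-30 was at -2.34 ± 0.087 on the probe used, against -0.48 to 0.37 on its other 3 probes. Of 275 nuclear hormone receptor genes, 69 fell and 27 rose (camera adjusted p = 0.0232; adjusted p = 0.478 with an estimated correlation), with nhr-225 (-1.27 ± 0.10) and nhr-57 (-0.90 ± 0.069, with its other 7 probes at -0.91 to -0.35) lower and nhr-178 (2.30-fold) and nhr-241 (2.13-fold) higher. Adjusted over each list alone, 34 collagen genes, 35 hedgehog-related genes and 67 receptor genes fell.

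CDK-8 acts on EGF receptor signalling in vulval development, so that pathway was examined as well. Of 23 genes of the EGF, Ras and ERK pathway and its vulval fate outputs, 7 fell and 2 rose (camera adjusted p = 0.283, fry adjusted p = 0.00254). With an estimated correlation the camera adjusted p was 0.523. The mean of the list was lower by 0.17 (-0.17 ± 0.028, SE over arrays), without overlap between the arrays of the strains. As the list pools components with outputs, its mean gives no direction of pathway activity. The RNA came from whole worms, so these values do not speak for vulval cells alone. The Hox gene lin-39 (-0.82 ± 0.082), the rhomboid gene rom-1 (-0.52 ± 0.068), the kinase gene mek-2 (-0.34 ± 0.067) and the Ras exchange factor gene sos-1 (-0.61 ± 0.14) fell. Of 24 Notch genes and EGF pathway inhibitors, 2 rose and 3 fell (camera adjusted p = 0.840). Here sel-8, which encodes a nuclear partner of the Notch receptor, rose 7.24-fold (2.86 ± 0.29), with mutant arrays between 12.46 and 13.74. The presenilin gene hop-1 (0.34 ± 0.064) rose, and the presenilin gene sel-12 (-0.36 ± 0.079) and the receptor gene lin-12 (-0.33 ± 0.067) fell. In both lists the counts were the same adjusted over the list alone.

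Stress, insulin and immune genes held large single changes, and none of these lists was past the camera threshold, which compares a list with all other genes. Of 57 chaperone genes, 7 rose and 12 fell (camera adjusted p = 0.499), with the small heat shock gene sip-1 (2.17 ± 0.11, 3 mutant arrays) higher and hsp-16.2 (-1.48 ± 0.10), hsp-16.41 (-1.26 ± 0.10) and hsp-6 (-0.62 ± 0.077) lower. The hsp-16 genes are similar copies. Of 52 metal and oxidative stress genes, 10 rose and 14 fell (camera adjusted p = 0.501). The ferritin gene ftn-1 rose 4.54-fold and the metallothionein gene mtl-1 1.96-fold, while the cadmium-responsive gene cdr-1 fell 4.53-fold and numr-1 2.14-fold. Of 29 genes of the insulin pathway and outputs of DAF-16, a FOXO factor, 11 rose and 6 fell (camera adjusted p = 0.439). The mean of this list was nevertheless higher in the mutant by 0.35 ± 0.038 (SE over arrays). The list passed by fry (fry adjusted p = 0.00037) but not by camera with an estimated correlation (camera adjusted p = 0.910). As it pools pathway components with outputs, its mean gives no direction of pathway activity. The median change was only 0.14, and 5 members rose 2-fold or more, with lea-1, dod-24 (2.24 ± 0.14) and nnt-1 (2.03 ± 0.071) higher and sams-1 lower on the probe used (-1.01 ± 0.069) but at 0.01 on its second probe. Of 40 insulin-like peptide genes, 9 rose and 12 fell (camera adjusted p = 0.734), with ins-20 (2.56 ± 0.12, a lower limit since its wild-type signal was low) and ins-4 (1.62 ± 0.088) higher and ins-9 (-1.40 ± 0.079) and ins-33 (-1.52 ± 0.088) lower. Of 129 lysozyme, saposin and pathogen response genes, 34 rose and 36 fell (camera adjusted p = 0.608), with spp-12 higher and asp-17, irg-1 and fipr-10 (-2.55 ± 0.099) lower. Adjusted over the list alone, the rises and falls were 7 and 12 chaperone, 10 and 14 metal stress, 11 and 7 insulin pathway, 10 and 12 insulin-like peptide and 36 and 38 lysozyme and pathogen response genes.

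The other lists did not pass the camera threshold. Of 31 muscle genes, 6 rose and 3 fell (camera adjusted p = 0.669), of 23 intestine genes 4 rose and 4 fell (0.813), and of 23 epidermis and seam genes 3 rose and 6 fell (0.620). Markers of other worms in the sample were also below the threshold, with 5 of 46 early embryo genes higher and 6 lower (camera adjusted p = 0.734) and 0 of 13 male neuron and tail genes higher and 3 lower (0.377). However, 29 of the early embryo genes and 6 of the male genes were not well above background on any mutant array. These lists therefore say little about embryos or males in the sample. The counts of rises and falls were 10 and 2 of 34 cell cycle genes (camera adjusted p = 0.265), 4 and 5 of 28 Wnt signalling genes (0.696), 4 and 4 of 29 vulva and uterus genes (0.831) and 8 and 8 of 33 moulting genes (0.734). They were 17 and 14 of 51 ABC transporter genes (camera adjusted p = 0.831), 66 and 51 of 249 C-type lectin genes (0.997), 6 and 2 of 22 epidermal antimicrobial peptide genes (0.377), 106 and 71 of 498 F-box and MATH-BTB genes (0.815) and 86 and 82 of 1518 chemoreceptor genes (0.831). Of the chemoreceptor genes, 1087 were not well above background on any mutant array. In housekeeping groups, 1 rose and 0 fell of 75 ribosomal protein genes (camera adjusted p = 0.534), 1 and 1 of 33 proteasome genes (0.447), 3 and 4 of 44 respiratory chain genes (0.960) and 2 and 2 of 29 transcription and splicing genes (0.831). Adjusted over the list alone, the rises and falls were 5 and 2 for muscle, 5 and 6 for the early embryo, 0 and 1 for male genes, 3 and 5 for Wnt signalling, 4 and 3 for the vulva, 9 and 8 for moulting, 17 and 16 for ABC transporters, 66 and 54 for C-type lectins, 47 and 43 for chemoreceptors, 1 and 3 for the respiratory chain and 0 and 0 for transcription and splicing, while F-box genes had 1 rise and 1 fall fewer. In the other lists of this paragraph they were the same as over all genes. Median, mean and camera direction differed in sign in the lists of cytochromes P450, UDP-glucuronosyltransferases, Notch genes, insulin-like peptides, ABC transporters, C-type lectins, vulval genes, intestine genes and chemoreceptors, so no direction is given for them.

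Arrays of a strain resembled each other more than arrays of the other strain. Slides and batches were not compared, so a difference between them cannot be told apart from that of the strains here. Across the 18554 genes with a value on all 8 arrays, which are not independent replicates, the Pearson correlation was 0.9950 to 0.9976 within wild type, 0.9951 to 0.9964 among mutant replicates 1 to 3, and 0.9744 to 0.9855 between strains. The distance between strains exceeded that within strains more than in any other split of the 8 arrays (1 of 35 splits, exact permutation p = 0.0286, the smallest this design allows). Mutant replicate 4 correlated with the other mutants at 0.9882 to 0.9890, below the range of the other pairs within a strain. A first component held 62.3% of the variance and separated the strains. The next held 16.9% and set mutant replicate 4, at 43.5, apart from the other mutants, at -20.84 to -14.04.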

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

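The tests on the germline and yolk pattern were chosen after the result was seen, and those on mutant replicate 4, on neighbouring genes and on splits of the arrays before.

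The counts of changed genes were set against other splits of the 8 arrays into 4 and 4. The real split gave 7753 changed genes and the highest of the other splits gave 0, so that 1 of 35 splits reached the count. For genes changed 2-fold, the real split gave 1369 and the highest other 0, again 1 of 35 splits. The other splits place both strains in each group, so that the strain difference adds to their spread. Their counts of 0 are therefore no measure of what chance gives, and these splits cannot exclude chance. For gene lists past the camera threshold, 4 of 35 splits gave 13 or more, the highest of the others being 13. The others that reached 13 had 1 or 3 mutant arrays in the first group, so part of the strain difference remained between groups. Splits with 2 mutant arrays in each group gave 1 to 8 lists. The splits therefore cannot decide whether chance gives the number of lists, and chance is not excluded.

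Most measured sperm, oocyte and germline genes rose, while the mean of the vitellogenin list was lower by 3.44 (-3.44 ± 0.081, SE over arrays). None of these lists passed with an estimated correlation (adjusted p = 0.194 to 0.478). Older mutant worms as the only cause were argued against by this fall, since yolk genes climb towards adulthood. Younger worms as the only cause were argued against by the oocyte and eggshell list, which was higher by 0.42 ± 0.054. Males alone, which make neither oocytes nor yolk, were argued against by the gap of 3.86 ± 0.056 between the shifts of these lists. These comparisons use the lists that make up the pattern. They cannot exclude a difference in age or in the share of males combined with a separate change of yolk genes. The hedgehog-related and moulting lists were fixed as signs of timing within the larval stage. Their shifts were -0.20 ± 0.033 and -0.04 ± 0.051 (SE over arrays). Many of these genes cycle with the moults, so their shifts do not tell older from younger worms. If a larger germline share of the RNA were the whole cause, all somatic lists would fall alike. The muscle list exceeded the neuron list by 0.34 ± 0.11 (0.25 ± 0.080 without mutant replicate 4). Among the tissue marker lists these had the highest and lowest shifts, 0.11 ± 0.090 and -0.23 ± 0.073. The intestine (-0.009 ± 0.076) and epidermis (-0.07 ± 0.061) lists lay between them. Comparing the extreme lists favours a gap, so it is only weak evidence against germline share as the whole cause. An effect of the cdk-8 mutation on yolk and germline gene expression may lie behind part of the pattern. This is a hypothesis found and tested on the same data. A change in age or in germline share, combined with another difference between the strains, stays open.

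Mutant replicate 4 lay apart from the other 3 mutant arrays in 5 measures. It had 4214 empty cells against 0, 62.0% of probes well above background against 72.7% to 74.4%, 4223 probes with an outlier flag against 1308 to 1787, a score of 43.5 on the second component against -20.84 to -14.04, and an SD of 0.457 around the other mutants against 0.263 to 0.283. In the 52 array columns with under 5% empty spots, its SD was 0.917 times the highest of the other mutant arrays, while in the remaining columns it was 0.658 against 0.280 to 0.311. Over the brighter part of the probes its SD was 0.757 times the highest of the others, while over the dimmer part it was 0.606 against 0.319 to 0.328. Both results are consistent with noise in dim spots in the part of the array where spots were flagged as a cause of its spread. They do not explain why bright lists were higher on this array than on the mean of the other mutants, by 0.39 for the respiratory chain, 0.31 for the proteasome and 0.39 for the major sperm proteins (range of the other mutants 0.075, 0.016 and 0.060). That part is left open, and no biological explanation was tested.

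Genes changed 2-fold lay beside each other on the chromosomes, with 187 neighbouring pairs changed the same way against 49.7 on average in 10000 shuffles (permutation p = 1e-04, the smallest they can give). Similar probes that bind the same transcript were argued against as the whole cause, since 176 pairs whose probes share no run of 16 bases remained against at most 78 in shuffles. Chromosome carried over with the cdk-8 allele was argued against as the whole cause as well, since 156 pairs lay outside chromosome I against at most 66. The share of 2-fold genes within 2 Mb of cdk-8 was 8.18%, against 6.76% elsewhere (Fisher's exact p = 0.111, 2-sided). Shared regulation of gene clusters, operons or other inherited differences between the strains may contribute and were not tested.

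Among 227 groups of 4 values of 117 named genes, 12 (5.29%) held 1 array far from the other 3, and chance gives about 1 in 20. Wild-type replicate 3 gave 11.30 for nlp-4 (others 10.99 to 11.03), 6.75 for oac-11 (6.06 to 6.09), 11.62 for mdt-1.2 (11.75 to 11.78), 12.18 for msp-142 (12.31 to 12.33) and 13.46 for acox-1.2 (13.40 to 13.41). Wild-type replicate 4 gave 13.12 for grl-27 (13.44 to 13.48), 9.98 for ins-4 (9.89 to 9.90) and 11.51 for tbh-1 (11.84 to 11.87), and wild-type replicate 1 gave 18.02 for acdh-1 (17.91 to 17.93). Mutant replicate 3 gave 9.97 for cyp-35B3 (9.39 to 9.45), mutant replicate 1 gave 10.15 for ptr-22 (10.31 to 10.33) and mutant replicate 4 gave 12.86 for ugt-1 (12.66 to 12.67).

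Probes outside the gene test also differed between the strains. Of 6907 probes that name no gene, 1113 were changed, and of 1277 probes that name several genes, 612 were.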

How the results depend on the processing

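Normexp correction, detected genes, genes with all 8 values and removal of flagged spots were chosen after the data were examined. Genes changed numbered 5368 to 8535 under the alternatives run on 1 value per gene, and 13877 (6846 higher, 7031 lower) when every probe was tested, which follows from the 43603 values tested. Genes changed 2-fold numbered 1192 to 1547. The shift to a common 75th percentile and quantile normalization each gave 7753 genes changed and 1369 changed 2-fold, as without them. All columns already shared 1 distribution, so these settings could change almost nothing and are no check. Leaving out 1 array gave 6454 to 7799 genes changed, 1192 to 1461 changed 2-fold, 11 to 13 lists and a cdk-8 change of 0.53 to 0.65. No list passed with an estimated correlation (0 of 43), 24 did by fry. C-type lectins and chemoreceptors had no call by camera, which compares a list with all other genes (camera adjusted p = 0.997 and 0.831). By fry, which does not, they passed upward (fry adjusted p = 0.0101 and 0.0131). The mean change of all measured members was 0.044 and 0.043, so camera's downward label is relative to other genes and is no fall of these lists. Over the members with a value on all 8 arrays, which fry tested, the shift was 0.023 ± 0.033 and 0.055 ± 0.033 (SE over arrays). Without mutant replicate 4 it was -0.0019 and 0.022. Of the 1518 chemoreceptor genes, 1087 were not well above background on any mutant array. No rise of these lists is therefore claimed. Fatty acid oxidation lost its call without the dimmest genes (adjusted p = 0.0608), without flagged spots (0.161) and with detected genes only (0.0599). Among genes picked by the naming rule, 54 calls were lost in the settings fixed beforehand and 2 in those added, and no gene changed direction. The replicate number as a block gave 6061 genes changed, of which 6006 were shared with the fit without it, 1348 changed 2-fold and 13 lists. Deviations of arrays with the same number correlated at 0.00, -0.07, -0.22 and -0.07, which gave no sign that the numbers pair the arrays. Not run were normexp on scanner signals and slides as blocks, which need wild-type scanner files, and a pseudocount, since the table is in log2. No background was subtracted, so changes of dim genes are understated.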

Other observations

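All tests in this part were chosen after the data were examined. Chromosomes differed in the direction of change. Among 1903 X-linked genes with a wild-type mean at least 2 (log2) above the lowest detected signal, 13.9% rose and 28.8% fell, while among 11679 autosomal genes 27.2% rose and 21.3% fell. The median change was -0.10 on the X chromosome and 0.03 on the autosomes, a difference of -0.13 (exact permutation test over 70 assignments of the arrays, 2-sided p = 0.0286, the smallest they can give). The difference was -0.12 without the germline, sperm, oocyte, histone and cell cycle lists and -0.10 after cyclic loess normalization. These lists do not hold all germline genes, so leaving them out cannot tell whether the germline rise contributes to the difference.

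Gene families grouped by name were tested with camera, over 177 families of at least 10 members. Past the threshold were 28 families, 7 higher and 21 lower, and 0 were with an estimated correlation (lowest adjusted p = 0.531). The median of each of the 28 kept its sign after cyclic loess normalization. All 12 nspc genes, a nematode-specific peptide family, fell (median -1.35, camera adjusted p = 8.80e-07), as did 12 of 16 idpp genes (median -0.71, camera adjusted p = 0.000191). Of 33 slc genes, which encode solute carriers, 17 fell and 1 rose (median -0.23, camera adjusted p = 0.000263), and of 54 lgc genes, which encode ligand-gated ion channels, 21 fell and 2 rose (median -0.24, camera adjusted p = 0.000191). Of 36 nas genes, which encode astacin proteases, 21 fell and 5 rose (camera adjusted p = 0.00206). Higher families besides sperm genes and histones were bath, which is part of the fixed F-box and MATH-BTB list (20 of 41 rose, camera adjusted p = 0.00426), him, which overlaps the germline list (9 of 11 rose, camera adjusted p = 0.00353), vha, the subunits of the vacuolar proton pump (9 of 19 rose, camera adjusted p = 0.0241), and nep, genes of neprilysin-like peptidases (14 of 26 rose and 5 fell, median 0.53, camera adjusted p = 0.038).

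Runs of neighbouring genes changed together. On chromosome V, the 6 neighbours T28A11.18, T28A11.19, T28A11.5, T28A11.20, T28A11.4 and T28A11.3 rose by 1.43 to 3.44 (log2), and the 5 neighbours exh-1, C36C5.12, C36C5.14, C36C5.4 and C36C5.15 rose by 1.46 to 6.06. On chromosome I, acd-2, acd-1 and delm-2 rose by 2.42 to 3.86. These runs were picked after their values were seen, and probes next to each other in them shared no run of 16 bases.

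Rises outnumbered falls near 2-fold. Within 0.25 (log2) of a 2-fold change lay 1494 genes that rose and 512 that fell, while between 0.25 and 0.75 there were 2176 that rose and 2501 that fell. Of the 62 measured members of the sperm lists, 46 rose by an amount within 0.25 of 2-fold.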
